A study of Mus musculus with 6 samples.

How the data were processed

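DNA methylation was profiled in mouse hematopoietic cells by MBD2 pulldown followed by sequencing. MBD2 is a protein whose methyl-CpG-binding domain holds methylated DNA, so the bound fraction is enriched for fragments carrying methylated CpG sites, and the unbound fraction stays in the supernatant. Per the labels' protocols, cells came from adult female C57BL/6 bone marrow. Stem cells (HSC) were sorted as lineage-negative cells positive for both Sca-1 and c-kit, and common myeloid progenitors (CMP) as lineage-negative cells without Sca-1 and with c-kit. HSC and CMP are the labels' names for these gates, and other cells that the gates could hold were not examined. How the erythroblasts (ERY) were obtained is not given in the sources used here. Each of the 3 cell types has 1 MBD2-enriched library and 1 supernatant library among the 6 samples of the series. The 3 supernatant libraries are not analysed here.

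Per the labels' protocols, libraries were sequenced on an Illumina Genome Analyzer as 36 bp single-end reads, and uniquely placed reads defined the bound part of the genome. The genome build was mm9, per the submitters' processing notes. The authors deposited 1 peak list per cell type for the enriched libraries, exported from a genome browser's table query per the file headers. Each deposited list has 3 columns, namely chromosome, start and end, and holds no height, score, enrichment or p-value. The aligner, the peak caller, its threshold and whether the supernatant served as its control are not given in the sources used here. The depth of each library is unknown, so no floor or interval that depends on read numbers is given. A position outside a list is therefore a position where no peak was called, not one shown to be free of methylation.

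Coordinates are printed 1-based on mm9. The gene table at hand belongs to a different assembly, GRCm38, so its positions were not used, and regions are named by coordinates only. For the same reason the planned comparisons of promoters and other gene features, of fixed gene lists and of ETS motif density were not run.

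Peaks of 2 lists were called overlapping when they shared at least 1 bp. A peak of an earlier list is called kept when it overlaps a peak of the later list and absent otherwise. Peaks of all 3 lists that overlapped or touched were merged into regions, and each region was put into 1 of 7 classes by the lists with a peak in it. Regions with a peak in the earlier list and none in the later one are called lost, and the reverse gained. Chance overlap was taken from 100 shuffles of the second list within the part of each chromosome spanned by peaks, keeping widths. Peaks cluster along the genome for reasons that such shuffles do not hold constant, so the shuffled share is a low baseline. Chromosome X was compared with the 19 autosomes singly, with 1000 draws of autosomal peaks matched to X by width decile, and with runs of consecutive autosomal peaks as long as the X list. These draws and runs were chosen after the data were seen.

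With 1 library per cell type, no difference between cell types has a replicate check, and no test between cell types was run. Shares carry 95% exact binomial (Clopper-Pearson) intervals. These treat peaks as independent and cover counting error only, not the variation between animals, sorts, pulldowns or libraries. The width of a peak is used as the single property each list gives.

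The regions named were chosen by a rule fixed before the data were examined. For each of the 3 comparisons, the rule took the 5 widest peaks of the earlier list that overlap none of the later list, the 3 widest in the other direction, and the 2 chromosomes with the highest and the 2 with the lowest ratio of covered bases. The peaks were ranked by width alone, and repeats or ease of read mapping at the named positions were not examined. Alternatives covered the overlap rule, the wider 50% of each list, autosomes alone, leaving out each chromosome, merging within 500 bp, 1 kb bins and lists reduced at random to equal length.

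Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The overlap functions were checked against bedtools 2.31.1 and gave identical counts on the deposited lists. They were also tested on simulated data made from the HSC list. Where 30.0% of 83433 peaks outside X had been kept, 30.2% were found. Where 60.8% of 2364 X peaks had been kept, 60.8% were found.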

Results

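Methylated DNA was mapped in 3 stages of mouse hematopoiesis, namely stem cells (HSC), common myeloid progenitors (CMP) and erythroblasts (ERY), the nucleated precursors of red cells. The series' design asks how methylation profiles change as stem cells differentiate. Each stage was represented by 1 MBD2-enriched library and its list of peaks, without read counts. The HSC list held 85797 peaks, the CMP list 50638 and the ERY list 27839. All peaks lay on the 19 autosomes, X or Y. The depth of the libraries is unknown, so a region called lost below is one without a peak in the later list, at whatever sensitivity that list had.

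The number of methylated peaks was lower at each successive stage. CMP had 59.0% as many peaks as HSC, ERY had 55.0% as many as CMP, and ERY thus had 32.4% as many as HSC. The covered length showed the same order, with 69.5 Mb in HSC, 43.6 Mb in CMP and 23.0 Mb in ERY. The ERY total was 3.03-fold lower than that of HSC. Individual peaks were of similar size in the 3 lists. The median width was 748 bp in HSC (interquartile range 592 to 942), 818 bp in CMP (671 to 956) and 788 bp in ERY (661 to 903). The lists differed in the number of peaks far more than in their width. No replicate library was at hand, so these differences have no replicate check.

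The peaks of the later stages lay almost entirely within those of the HSC list. In the CMP list 96.5% of peaks (95% interval 96.3 to 96.6%) overlapped an HSC peak, and in the ERY list 95.3% did (95.1 to 95.6%). Shuffled HSC peaks gave 5.69% for CMP and 5.60% for ERY. In the other direction, 57.1% of HSC peaks (56.8 to 57.5%) were kept in CMP and 30.9% (30.6 to 31.2%) in ERY, against 3.39% and 1.86% for shuffled lists. Of the CMP peaks, 50.7% (50.2 to 51.1%) were kept in ERY, against 1.92% for shuffled lists. Of the ERY peaks, 92.5% (92.2 to 92.8%) overlapped a CMP peak. With the wider 50% of each list, the shares inside the HSC list were 74.5% for CMP and 77.5% for ERY. With both lists of a pair reduced at random to the length of the ERY list they were 31.7% and 31.2%, and 31.6% of HSC peaks were kept in CMP and 30.9% in ERY. Removing peaks from the overlapped list, by the width cut or at random, lowers such shares by construction. Neither set of reduced values thus bears on the nesting. The closeness of the kept shares for CMP and ERY at equal length also follows by construction, since nearly all peaks of both lists lie inside the HSC list.

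Merging the 3 lists gave 87514 regions. Of these, 35650 (40.7%, interval 40.4 to 41.1%) had a peak in HSC alone, 23076 (26.4%, 26.1 to 26.7%) in HSC and CMP, and 24935 (28.5%, 28.2 to 28.8%) in all 3 cell types. The remaining 4 classes were small. Regions with a peak in CMP alone numbered 1503, those in ERY alone 1013, those in HSC and ERY but not CMP 1054, and those in CMP and ERY but not HSC 283. The class counts depended on the peaks used. With the wider 50% of each list, HSC alone, HSC with CMP, and all 3 held 22106, 9878 and 8770 regions. The cut also moves regions between classes by construction, since a peak below it no longer counts.

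**Figure D1:**
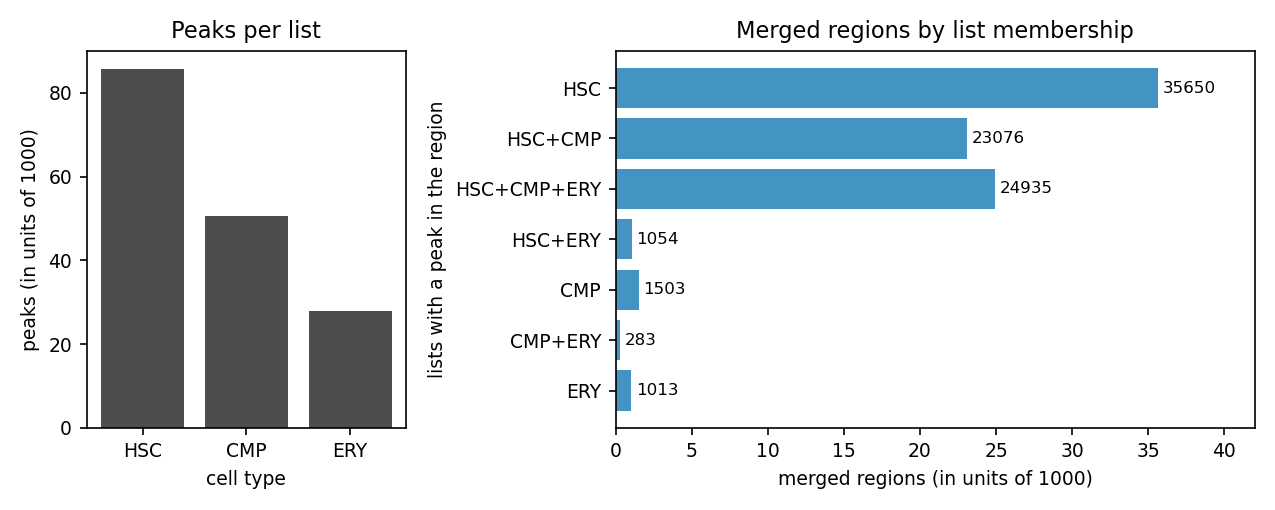
Left, the number of peaks (in units of 1000) in each cell type's list, 1 library each. Right, the number of merged regions (in units of 1000) by the set of lists with a peak in the region, with the count printed at each bar. HSC alone, HSC with CMP, and all 3 lists hold 35650, 23076 and 24935 regions, and no other class exceeds 1503.

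For the step from HSC to CMP, lost regions far outnumbered gained ones. A total of 36704 regions with an HSC peak had none in CMP, while 1786 had a CMP peak and none in HSC, a ratio of 20.6 to 1. The widest HSC peaks without a CMP counterpart lay on chromosome 11 at 102637003 to 102639935 (2933 bp) and 87614480 to 87617309 (2830 bp). The next were on chromosome 8 at 48862236 to 48864827 (2592 bp) and 119632508 to 119634963 (2456 bp), and on chromosome 17 at 6960796 to 6963211 (2416 bp). None of these 5 had a peak in ERY either. The widest CMP peak without an HSC counterpart, on chromosome 15 at 74915809 to 74917790 (1982 bp), also had a peak in ERY. The next widest, on chromosome 19 at 6541475 to 6542827 (1353 bp) and on chromosome 15 at 27495833 to 27497171 (1339 bp), had none. The ratio of lost to gained depended on the peaks used. Among the wider 50% of each list, 24002 regions were lost and 6451 gained. The cut itself turns shared regions into gained or lost ones. A CMP peak over an HSC peak below the cut counts as gained, and an HSC peak over a CMP peak below it as lost.

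For the step from CMP to ERY, 24579 regions were lost and 2067 gained, a ratio of 11.9 to 1. The widest CMP peaks absent from ERY all overlapped an HSC peak. They lay on chromosome 11 at 3049311 to 3059243 (9933 bp) and 2999965 to 3005132 (5168 bp), on chromosome 6 at 52152413 to 52157107 (4695 bp), on chromosome 7 at 38967866 to 38972053 (4188 bp) and on chromosome 9 at 3024127 to 3028044 (3918 bp). The peak on chromosome 9 is absent as a peak only, since the wider merged region around it holds an ERY peak and is not among the lost regions. The widest ERY peaks absent from CMP were on chromosome 12 at 19722697 to 19724706 (2010 bp), chromosome 5 at 136615060 to 136616953 (1894 bp) and chromosome 6 at 136855240 to 136856894 (1655 bp). The last 2 overlapped an HSC peak and the first did not. With the wider 50% of each list the counts were 14814 lost and 3489 gained, where the cut again turns shared regions into gained or lost ones.

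Over the whole course from HSC to ERY, 58726 regions were lost and 1296 gained, a ratio of 45.3 to 1. Of the lost regions, 60.7% (35650) already lacked a peak in CMP and 39.3% (23076) still had one there. An HSC peak that was kept in CMP was kept in ERY in 51.8% of 49020 cases (interval 51.4 to 52.2%). An HSC peak absent from CMP had an ERY peak in 3.06% of 36777 cases (2.89 to 3.24%). The widest HSC peaks absent from ERY all had a CMP peak. They lay on chromosome 11 at 2999952 to 3005230 (5279 bp), chromosome 6 at 52152373 to 52157118 (4746 bp), chromosome 8 at 91553577 to 91557374 (3798 bp), chromosome 19 at 7168448 to 7171808 (3361 bp) and chromosome 9 at 3008083 to 3011292 (3210 bp). The widest ERY peak absent from HSC was on chromosome 15 at 74915560 to 74917932 (2373 bp) and had a CMP peak. The next, on chromosome 12 at 19722697 to 19724706 (2010 bp) and chromosome 1 at 172872011 to 172873639 (1629 bp), had none. With the wider 50% of each list 31984 regions were lost and 3108 gained, where the cut again turns shared regions into gained or lost ones.

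Wide peaks were kept more often than narrow ones at every step. HSC peaks kept in ERY had a median width of 864 bp and those absent 706 bp. For HSC peaks kept in or absent from CMP the medians were 812 and 678 bp, and for CMP peaks kept in or absent from ERY 889 and 751 bp. A shared 1 bp is easier to reach for a wide peak. Requiring 50% of the peak to be covered made the difference in medians smaller, in the same direction. It went from 134 to 119 bp (HSC to CMP), 138 to 127 bp (CMP to ERY) and 158 to 135 bp (HSC to ERY). Of the narrowest 10% of HSC peaks (246 to 462 bp), 37.1% (interval 36.1 to 38.1%) were kept in CMP and 13.9% (13.1 to 14.6%) in ERY. Of the widest 10% (1180 bp and above), 85.1% (84.4 to 85.9%) were kept in CMP and 61.3% (60.2 to 62.3%) in ERY. Of CMP peaks, 29.7% (28.4 to 31.0%) of the narrowest 10% and 79.0% (77.9 to 80.2%) of the widest 10% were kept in ERY. Within the 24935 regions with a peak in all 3 cell types, the median covered length was 886 bp in HSC, 898 bp in CMP and 801 bp in ERY. ERY covered fewer bases than HSC in 65.1% of these regions, and CMP fewer than HSC in 49.8%.

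**Figure D2:**
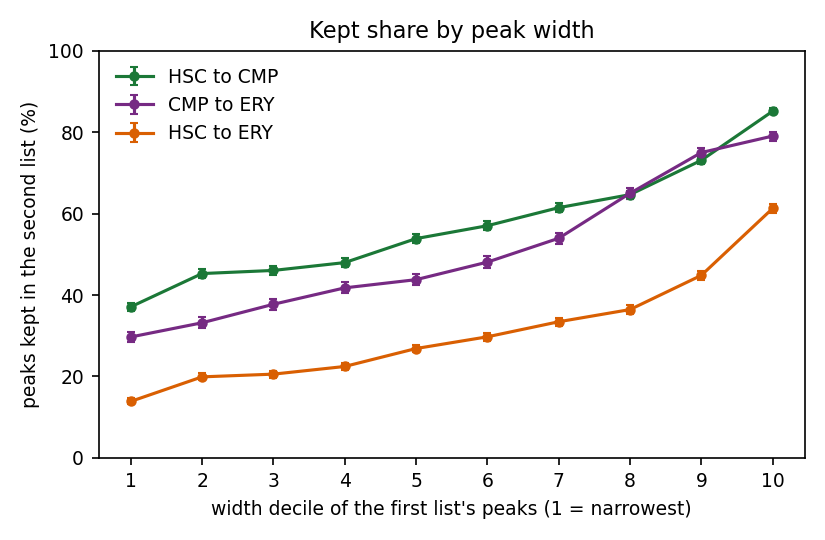
Percent of peaks of the first list that overlap a peak of the second list, by width decile of the first list (1 narrowest, 10 widest). Points are shares of 1 pair of lists, and bars are 95% exact binomial intervals. The share kept rises with width for each pair, from 13.9% to 61.3% for HSC to ERY.

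The share of peaks kept was similar across the autosomes and different on chromosome X, in opposite directions at the 2 steps. From HSC to CMP, X kept 64.0% of its peaks (interval 62.0 to 65.9%), above each of the 19 autosomes, which ranged from 54.9% on chromosome 6 to 59.4% on chromosome 7. From CMP to ERY, X kept 34.8% (32.4 to 37.2%), below each autosome, which ranged from 47.7% on chromosome 14 to 54.0% on chromosome 5. From HSC to ERY, X kept 23.2% (21.5 to 24.9%), again below the autosomal range of 28.6% to 33.2%. The standard deviation over the 19 autosomes was 1.10, 1.93 and 1.47 percentage points for the 3 pairs. X lay 7.02 points above the pooled autosomes in the first pair, and -16.4 and -7.95 points from them in the other pairs.

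The difference remained among peaks of like width. The median width of HSC peaks was 740 bp on X and 748 bp on the autosomes. Autosomal HSC peaks matched to X by width were kept in CMP at 57.3% on average (54.6 to 60.5% over 1000 draws) and in ERY at 31.8% (28.6 to 34.9%). Matched autosomal CMP peaks were kept in ERY at 51.8% (48.2 to 56.2%). Runs of consecutive autosomal HSC peaks as long as the X list gave 54.4 to 60.3% kept in CMP and 28.3 to 35.4% in ERY, and such runs of CMP peaks gave 47.5 to 56.8% kept in ERY. In each case the X value lay outside the range. Within regions that had a peak in all 3 cell types, the median ratio of ERY to HSC covered bases was 0.791 on X and 0.864 to 0.916 on the autosomes, while that of CMP to HSC was 0.982 on X and 0.980 to 1.03 on the autosomes. The ERY list also held more Y peaks than the others, 8 against 3 and 3, although all samples are labelled female.

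Among merged regions on X, 39.5% (interval 37.6 to 41.5%) were in the class of HSC and CMP without ERY, against 26.0% (25.7 to 26.3%) on the autosomes. Regions with a peak in all 3 cell types made up 22.2% (20.5 to 23.9%) on X and 28.7% (28.4 to 29.0%) on the autosomes. Regions in HSC alone made up 34.9% (33.0 to 36.8%) and 40.9% (40.6 to 41.2%). X also carried fewer peaks per Mb than any autosome in all 3 lists, with 14.5 in HSC, 9.67 in CMP and 3.46 in ERY. The lowest autosomal density was 25.5 in HSC, 15.1 in CMP and 7.98 in ERY, each on chromosome 14.

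**Figure D3:**
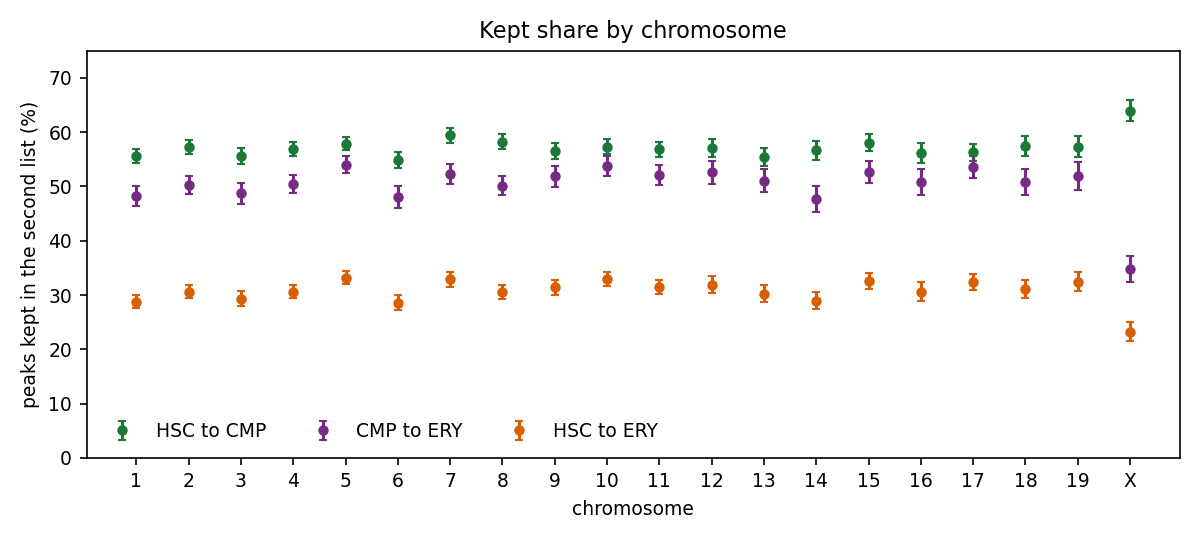
Percent of peaks of the first list that overlap a peak of the second list, by chromosome, for the 3 pairs of lists. Points are shares of 1 pair of lists, and bars are 95% exact binomial intervals. X lies at 64.0% for HSC to CMP, 34.8% for CMP to ERY and 23.2% for HSC to ERY, outside the autosomal range each time.

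In covered bases, CMP as a share of HSC was highest on Y (112%) and X (71.9%) and lowest on chromosomes 6 (59.9%) and 3 (60.9%). ERY as a share of CMP was highest on Y (337%) and chromosome 5 (56.2%) and lowest on X (33.3%) and chromosome 1 (50.1%). ERY as a share of HSC was highest on Y (377%) and chromosome 7 (36.1%) and lowest on X (23.9%) and chromosome 6 (30.4%). The values for Y rest on 3 peaks in HSC, 3 in CMP and 8 in ERY.

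The difference extended along X. In windows of 10 Mb, 16 of 17 X windows kept a larger share of HSC peaks in CMP than the median autosomal window (56.7%), and 16 of 17 kept a smaller share in ERY than the median autosomal window (30.4%). The X windows ranged from 56.3 to 69.9% kept in CMP and from 16.7 to 31.6% kept in ERY. The highest share kept in ERY was in the distal window, from 160 Mb to the end, with 31.6% of 95 peaks (interval 22.4 to 41.9%).

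**Figure D4:**
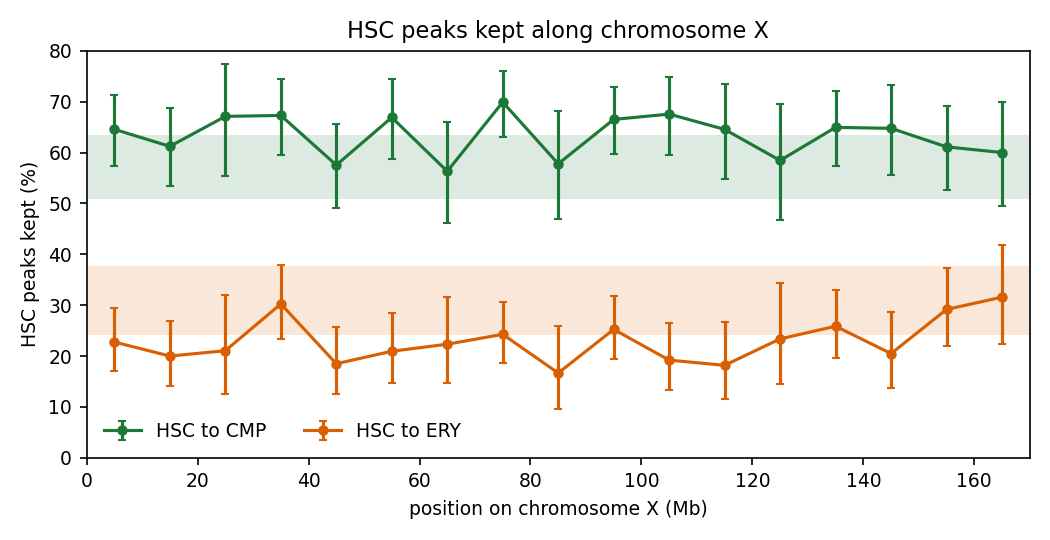
Percent of HSC peaks on chromosome X that overlap a CMP peak (upper points) or an ERY peak (lower points), in windows of 10 Mb along the chromosome. Bars are 95% exact binomial intervals, and shaded bands span the 5th to 95th percentile of autosomal windows of the same size. X windows range from 56.3 to 69.9% for CMP and from 16.7 to 31.6% for ERY.

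Peaks were clustered along the genome. In HSC 51.0% of peaks had another peak of the list within 5 kb, in CMP 38.5% and in ERY 30.0%. The median gap between neighbouring peaks was 10659.5 bp in HSC, 19093 bp in CMP and 32564 bp in ERY. Both measures depend on the number of peaks in a list, and no chance value was computed for them. They therefore do not rank the strength of clustering between cell types. HSC peaks absent from ERY lay within 5 kb of a kept HSC peak in 21.1% of cases, against 10.6% when their positions were shuffled. For HSC peaks absent from CMP the values were 33.2% and 18.1%, and for CMP peaks absent from ERY 20.2% and 10.3%. These excesses came with the clustering of all peaks. When instead the kept and absent peaks were exchanged at random within each chromosome, the expected shares were 22.3%, 35.7% and 23.2%, and each observed share lay below the lowest of 100 exchanges (22.0%, 35.2% and 22.8%).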

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

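The ERY list holds 8 peaks on chromosome Y, although the labels give female mice for all libraries. The HSC and CMP lists hold 3 each. This was singled out because Y was left out of the comparison of kept shares between chromosomes. All 3 lists have a peak near the start of Y, in ERY at 29339 to 29872. The other ERY peaks lie at 30118 to 30934, 38339 to 38899, 267675 to 268264, 406069 to 406551, 456198 to 456939, 2618726 to 2619356 and 2680908 to 2681558. The first of these other peaks overlaps a CMP peak at 30121 to 30750. The Y peaks are weighed in the closing observations together with chromosome X.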

How the results depend on the processing

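Chosen after seeing the data were the exchange of kept and lost labels and, for the X difference in kept peaks, the wider 50%, 50% of the peak covered, the width-matched draws and the runs of autosomal peaks. Only the clustering result changed direction. CMP had fewer peaks than HSC and ERY fewer than CMP under each alternative run, and X differed from the autosomes in the same direction under each alternative run for it. Leaving out each chromosome in turn left 359 of 360 values inside their interval (shares) or within 1.5 times (counts of peaks and regions). The counts could not fail this, since each chromosome holds a small part of the peaks, so only the shares were put to a check. The exception was the share of CMP peaks kept in ERY, which ranged from 50.4% to 51.2%, highest without X, and was also 51.2% on autosomes alone. With the wider 50% of each list, peak counts were 42978 in HSC, 25368 in CMP and 13968 in ERY, by construction. The shares kept were then 44.1% (HSC to CMP), 41.0% (CMP to ERY) and 25.2% (HSC to ERY). These fall by construction, since an earlier peak over a later peak below the cut counts as absent. Against the full later lists, the widest 10% of peaks were kept at 85.1%, 79.0% and 61.3%. Lost and gained regions were 24002 and 6451, 14814 and 3489, and 31984 and 3108 for the same steps. The gained ones rise by construction, since a later peak over an earlier peak below the cut counts as gained. An earlier peak over a later peak below the cut counts as lost in the same way. Regions in HSC alone, in HSC and CMP, and in all 3 numbered 22106, 9878 and 8770. Requiring 50% of the peak to be covered gave 55.5%, 49.2% and 29.1% kept, and requiring 50% of both 53.4%, 48.3% and 28.4%. Allowing 500 bp gave 59.4%, 52.1% and 33.0%. Reducing lists at random to equal length gave 31.6% for HSC to CMP, where the CMP list is cut too, and left CMP to ERY at 50.7% and HSC to ERY at 30.9%, where only the first list is cut. The share of ERY peaks inside the HSC list was 77.5% in the wider 50% and 31.2% after that reduction, by construction. In 1 kb bins, lost and gained bins were 66352 and 8196, 47047 and 4909, and 104496 and 4202, and the 3 classes held 63862, 40634 and 43202 bins. For shifts not given above as by construction, the cause was not tested. The X difference was 10.6 points (HSC to CMP, kept peaks) and -23.3 points (CMP to ERY, covered bases, planned) in the wider 50%. Exchanging kept and lost labels turned the log2 ratio of lost peaks near kept ones negative, to -0.104, -0.203 and -0.0842, from 0.88, 0.97 and 0.99 with shuffled positions. Feature, gene list and motif results, and the alternatives that need a peak score, were not run. With no read depth, how far sensitivity sets the list lengths is open.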

Other observations

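The tests on peak sensitivity, on uniform loss, on peak width and on Y below were chosen after the result was seen, and those on single stretches of X, on covered length on X and on shifted edges were fixed before their result was seen.

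Methylated peaks were densest at the distal ends of the autosomes in each cell type. The distal 10 Mb of the 19 autosomes carried 61.0 HSC peaks per Mb, against 32.7 between the ends and 28.1 in the proximal 10 Mb, and 17 of 19 autosomes were denser there than over their whole length. In CMP the densities were 36.1, 19.2 and 17.2, and in ERY 20.4, 10.6 and 9.29. The share of HSC peaks kept in ERY differed little between these parts, at 32.3% distal, 30.9% between and 31.4% proximal. Among 583 windows of 1 Mb with at least 50 HSC peaks, the lowest ratio of ERY to HSC peaks was on chromosome 1 from 136000001 to 137000000, with 6 ERY and 55 HSC peaks. Next was chromosome 6 from 52000001 to 53000000, with 6 and 51, which also holds the HSC peak at 52152373 to 52157118 that ERY lacks. The highest was on chromosome 14 from 55000001 to 56000000, with 46 ERY, 57 CMP and 75 HSC peaks. These windows were picked for their values, so they are descriptions of single libraries.

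Peaks over 5 kb numbered 17 in HSC, 8 in CMP and 5 in ERY. The widest peak of HSC and of ERY was on chromosome 11, from 3080495 to 3100291 in HSC (19797 bp), with 19871 bp in ERY and 19960 bp in CMP. The widest CMP peak was on X from 166409964 to 166430042 (20079 bp). It overlapped peaks of 15881 bp in HSC and of 13550 and 9615 bp in ERY.

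The first pattern is the smaller lists of CMP and ERY, nested in that of HSC. A uniform loss of sensitivity over all chromosomes need not keep equal shares on X and the autosomes. It would do so only if their peaks were of like height, and the lists give no height. On X 23.2% of HSC peaks were kept in ERY against 28.6% to 33.2% on the autosomes, while CMP moved the other way. Without heights this difference does not decide on a uniform loss. A lower sensitivity of peak calling in the later libraries thus stays open. The kept share rose with width but reached only 61.3% in the widest 10% of HSC peaks, which does not decide the matter because width need not follow peak height, and no depth or height is at hand. A loss of methylation between the cell types may give the same lists, and with 1 library per type the 2 cannot be told apart.

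The second pattern is chromosome X, which kept more HSC peaks in CMP and fewer in ERY than the autosomes. Narrower X peaks are argued against, since the lowest of 1000 width-matched autosomal draws kept 28.6% in ERY, above the 23.2% of X. Leaving out any 10 Mb window left X at 23.5% or less. That outcome was fixed in advance, since no window held more than 206 of the 2364 HSC peaks of X, too few to bring X to 28.6%. A single stretch is argued against by the windows themselves. In 16 of 17, the share kept in ERY was below that of the median autosomal window (30.4%). Lower enrichment over X in the ERY library stays open: in regions of all 3 lists the median ratio of ERY to HSC covered bases was 0.791 on X and 0.864 to 0.916 on the autosomes, whereas for CMP the X ratio of 0.982 lay within the autosomal range of 0.980 to 1.03, but covered width need not follow enrichment, which the lists do not give. Cells with a single X and a Y in the erythroblast library are a candidate explanation of the X pattern in ERY, and X-specific loss of methylation in erythroblasts another. Y made up 1.40% (interval 0.60 to 2.73%) of the X and Y peaks of ERY, above 0.13% (0.03 to 0.37%) in HSC and 0.19% (0.04 to 0.55%) in CMP, but this share rises as X peaks fall, without the first 100 kb of Y (which holds a peak of each list) the interval of ERY (0.29 to 2.04%) overlapped those of HSC (0.01 to 0.31%) and CMP (0.0016 to 0.35%), and among all peaks the interval of ERY (0.0124 to 0.0566%) lay above that of HSC (0.0007 to 0.0102%) but overlapped that of CMP (0.0012 to 0.0173%), so the few Y peaks leave it open, and neither account addresses the higher share of X kept in CMP.

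The third pattern is the 1303 ERY peaks that overlap no HSC peak. Shifted edges of neighbouring HSC peaks are argued against for most of them, since only 7.14% (interval 5.80 to 8.67%) lay within 500 bp of an HSC peak. Shuffled positions gave 8.13%. That value also counts positions that fall on an HSC peak, which these peaks cannot do by definition, so it is no like baseline. Within 5 kb, 40.0% had an HSC peak, above the 27.9% of shuffled positions (highest of 100 shuffles, 31.4%), which again count positions on an HSC peak. Of the 1296 merged regions with an ERY peak and no HSC peak, 283 also held a peak of the separate CMP library. For ERY peaks as a whole, shuffled CMP lists gave 3.47%, a low baseline that is not matched to regions without an HSC peak. The sharing with CMP argues against independent chance calls as the source of the whole pattern. It does not show a gain of methylation, since a peak may have been missed in the HSC list. For the 1013 regions with a peak in ERY alone, gained methylation, peaks missed in the other lists and chance calls cannot be told apart from 1 library. The 1303 peaks were narrower than the other ERY peaks, with medians of 681 and 793 bp.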
